A study of Homo sapiens with 9 samples.

How the data were processed

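RNA was extracted from C4-2B cells on silica columns with DNase treatment, libraries were made from total RNA, and reads of 50 bp were sequenced from 1 end on an Illumina HiSeq, per the labels' protocols. Neither an enrichment for polyadenylated RNA nor a depletion of ribosomal RNA is given in the sources used here, and abundant non-polyadenylated RNAs are present in each library. The submitters' processing notes name TopHat, DESeq and the genome build hg38, without versions or settings; the counting tool, the annotation release and the use of strand are not given in the sources used here. Without strand, reads of a gene and of its antisense or overlapping partner cannot be told apart, and paralogs such as the histone genes can share reads.

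The deposited unit is RPKM, reads per kilobase of transcript and per M (mega, 1e6) mapped reads, which the authors gave for each RefSeq transcript in 1 file per library, per the file headers. The files use 2 transcript lists: 41740 transcripts for 6 libraries (DMSO replicate 1, the BET-kinase inhibitors, ENZ and JQ1) and 43202 for 3 (DMSO replicate 2 and both knockout libraries). The lists split the DMSO pair but follow the other groups, so that the list and any batch behind it cannot be separated from the knockout or from the inhibitors except through 1 DMSO library each. Each comparison is therefore also given with the list as a model term. Against DMSO this makes the same contrast for the knockout as leaving out DMSO replicate 1. For the BET-kinase, JQ1 and ENZ libraries it makes the same contrast as leaving out DMSO replicate 2. The list term and that omission are thus not separate checks.

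From these values, RPKM was summed over the transcripts of each gene. Symbols that differed between the lists were matched by transcript accession (176) or synonym (5), which left 19899 genes in both; 996 genes were in the shorter list alone and 1063 in the longer, and they were left out of the tests. Of the 19899, 17499 had the same transcripts in both lists. Depth was recovered from genes with 1 exon and 1 transcript, whose values are whole multiples of what 1 read is worth. Between 88.8% and 90.5% of such values above 0 came out whole within 0.02 reads, for 14.5 to 39.4 M mapped reads per library. Counts per gene were not recovered, since genes with several transcripts share reads. A read in a 1 kb transcript is worth 0.0254 to 0.0690 RPKM, so at 1 RPKM the number of reads is small and counting error is large, most of all in the BET-kinase and JQ1 libraries. Libraries of 1 group differed by far more than counting noise (chi-square per degree of freedom 171 to 1920), so none was a second copy of another.

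The design fixed before the data were examined named a count test first and limma for normalized values; since the unit is RPKM, limma was used. Genes with at least 1 RPKM in at least 2 libraries (12133) were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (limma-trend with a trended prior, Benjamini-Hochberg adjustment, threshold 0.05, two-sided). All 9 libraries entered a model with 5 groups and 4 residual degrees of freedom. The libraries labelled JQ1 and ENZ, with 1 library each, are assumed to vary like the replicated groups. Differences among the BET-kinase inhibitors used 7 groups, in which each inhibitor library stands alone and the DMSO and knockout pairs give 2 residual degrees of freedom. The labels do not say that libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. In the model with 5 groups that spread also holds differences between the 3 BET-kinase inhibitor libraries, which may be different compounds. It enters the tests of the knockout and of the libraries labelled JQ1 and ENZ as well. Their calls therefore depend on differences among the BET-kinase inhibitor libraries, which the model with 7 groups takes out of the spread. The knockout libraries are compared with DMSO-treated cells, and a Cas9 control without the HOXB13 edit was not analysed here.

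Gene lists (19, with 471 entries) were fixed beforehand: androgen response, luminal identity, histone and HEXIM1 genes, MYC and nucleolar genes, G2/M, DNA replication, nucleotide synthesis, chromatin assembly, BCL2 and IAP family, p53 targets, interferon, sterol synthesis, mesenchymal, neuroendocrine, ATF4 response, HOX clusters, BET and kinase genes, and 2 lists of other cell types (basal; stromal, blood and endothelial). Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one. The calls "adjusted over the list alone" use the p-values of the list's members only.

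Named genes followed a rule fixed beforehand: HOXB13, AURKB and MELK throughout; the 8 largest rises and falls in the knockout and BET-kinase comparisons and the 5 largest elsewhere, among called genes with a mean log2 of at least 1 and every library of the group beyond both DMSO libraries; the 3 largest called members per list; the 6 largest shared changes per direction; and a fixed set of androgen and BET marker genes. Not every gene so chosen is printed. Levels of KLK3, MYC, CDKN1A and DDIT3 and the change of INSIG1, given where the rule did not pick them, were chosen after their values were seen.

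The test was tried on simulated data drawn for the 12133 genes with 100 genes changed by each of 2 sizes. For the knockout it recovered 40% of genes changed by a log2 of 1 and 87% of those changed by 2, with 6 false calls among 133; for the BET-kinase inhibitors 63% and 92%, with 4 among 159. For the library labelled JQ1 it recovered 27% and 77%, and for that labelled ENZ 23% and 85%, so many changes of 2-fold are missed there. Chance likeness from shared controls was simulated with 50 draws of unchanged groups.

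Alternatives tried were quantile normalization, no filter, a mean of at least 5 RPKM, pseudocounts of 0.1 and 0.5, a log2 fold change of at least 1, 7 groups, only the groups compared, the replicate number as a block, and leaving out each library. Median scaling (alone and with an estimated correlation), the list term, genes with the same transcripts, the largest transcript per gene and leaving out libraries that enter a comparison only through the spread were added after seeing the data. Coordinates are those of the deposited files (hg38, counted from 1). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.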

Results

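RNA was sequenced from C4-2B cells, a prostate cancer line that models bone-metastatic, castration-resistant disease and grows without added androgen. The series asks which genes that depend on HOXB13, a homeobox transcription factor of the prostate lineage, also respond to inhibitors of the BET proteins, the bromodomain readers of acetylated histones. The 9 libraries comprised 2 of DMSO-treated cells, 2 of cells edited with CRISPR/Cas9 at HOXB13, 3 of cells given inhibitors labelled as BET-kinase inhibitors (MA4-022-1, MA4-022-2 and SG3-179), 1 labelled JQ1 and 1 labelled ENZ. JQ1 is a BET bromodomain inhibitor, and ENZ is read here only as the label gives it. The title and the treatment entry contradict each other for the last 2 libraries, since the one titled ENZ carries the BET-inhibitor treatment and the one titled JQ1 the anti-androgen treatment, so both are named by title as "the library labelled". Doses and times were not in the labels, and no treatment is given for the knockout libraries. The knockout libraries are titled KO1 and KO2 and are called replicates 1 and 2 here. Their titles do not say whether they are replicates of 1 edited line or separate lines.

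Depth, recovered from the smallest steps of the deposited RPKM values, was 25.2 and 36.0 M mapped reads for DMSO replicates 1 and 2 and 38.5 and 39.4 M for the knockout libraries. It was 15.2, 15.9 and 20.4 M for MA4-022-1, MA4-022-2 and SG3-179, 30.8 M for the library labelled ENZ and 14.5 M for that labelled JQ1. The inhibitor libraries other than ENZ were thus the shallowest. Principal component 1 (42.6% of the variance) separated the BET-kinase and JQ1 libraries from DMSO, and component 2 (33.7%) separated the knockout from the rest. The log2 difference between the DMSO libraries had an SD of 0.365 over genes, against 0.185 between the knockout libraries.

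HOXB13 itself (chromosome 17, 48724766 to 48728750, minus strand, hg38) was measured over the exons of its RefSeq transcript. It stood at 73.5 and 91.8 RPKM in DMSO and at 54.8 and 54.2 RPKM in the knockout, or 82.6 ± 12.9 and 54.5 ± 0.454 RPKM (mean ± SD, n = 2 each). The knockout libraries differed from DMSO by a log2 fold change of -0.58 ± 0.26 (SE), which did not pass the limma test (adjusted p = 0.125). It did pass with the spread taken from 7 groups instead of 5 (adjusted p = 0.0373) and with SG3-179 left out of the spread (adjusted p = 0.0343). The HOXB13 transcript was therefore still present in the knockout libraries, and its level does not check their labels, since an edit can end a protein without ending its RNA. HOXB13 fell under the BET-kinase inhibitors, to 41.4, 31.2 and 23.0 RPKM in MA4-022-1, MA4-022-2 and SG3-179 (log2 fold change -1.38 ± 0.23, adjusted p = 0.00181, limma). It fell to 25.9 RPKM in the library labelled JQ1 (-1.63 ± 0.32, adjusted p = 0.00496, limma), a call lost with quantile normalization (adjusted p = 0.0665). In the library labelled ENZ it was at 58.9 RPKM (-0.47 ± 0.32, adjusted p = 0.398, limma).

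**Figure D1:**
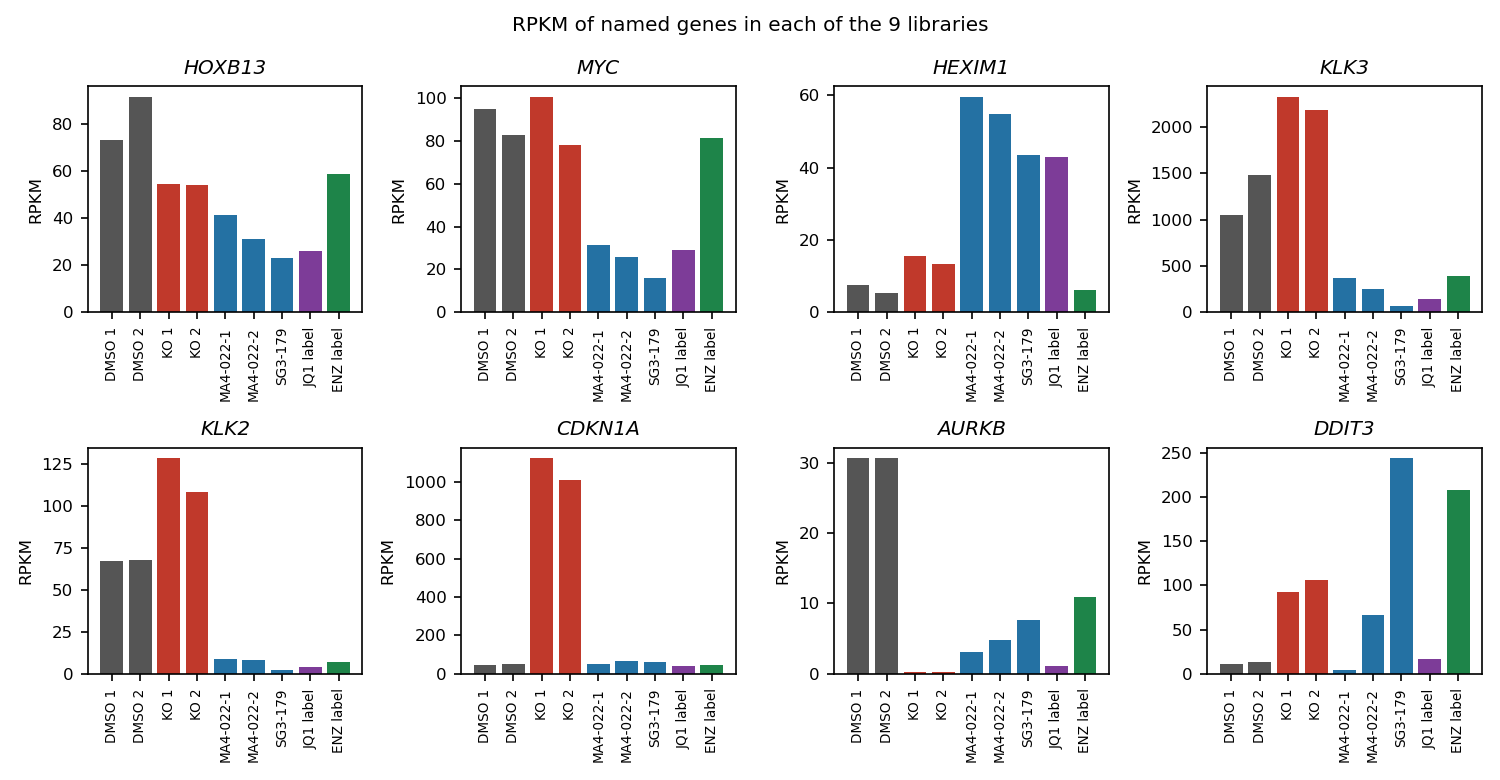
RPKM (vertical axis, from 0) of 8 named genes in each of the 9 libraries; each bar is 1 library, with DMSO in grey, knockout in red, the BET-kinase inhibitors in blue, and the libraries labelled JQ1 and ENZ in purple and green. CDKN1A reached 1123 and 1007 RPKM in the knockout libraries and was between 38.4 and 64.3 RPKM in the other 7, while HEXIM1 was at 42.9 to 59.6 RPKM in the BET-kinase and JQ1 libraries and at 5.45 and 7.57 RPKM in DMSO.

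The knockout was compared with DMSO to ask which genes change on loss of HOXB13. Genes of cell division fell and targets of p53 rose. The 8 largest falls were all replication-dependent histone genes of the chromosome 6 cluster, led by HIST1H3B (-7.89 ± 0.72), which went from 661 and 1292 RPKM to 3.47 and 2.42 RPKM, and HIST1H1B (-7.86 ± 0.71). HIST1H2AJ, HIST1H2AH, HIST1H2BO, HIST1H2AB, HIST1H3I and HIST1H2BM fell by 6.77, 6.37, 6.33, 6.28, 6.14 and 6.10 on the log2 scale. Those that encode the same type of histone resemble each other, so reads can be shared within a type. The largest rises included those of HMOX1, the heme-degrading stress enzyme (6.82 ± 0.86; 849 and 729 RPKM against 5.32 and 6.71), GDF15, a secreted stress cytokine (6.57 ± 0.55), and CDKN1A, which encodes the CDK inhibitor p21 (4.43 ± 0.18). SIPA1L2, TNFSF15, LPXN and TSC22D3, a glucocorticoid-induced gene, rose by 4.42, 4.40, 4.02 and 3.76. Each of these genes was beyond both DMSO libraries in 2 of 2 knockout libraries, which the rule for naming them required.

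Of 12133 genes tested, 1699 rose and 1578 fell at an adjusted p under 0.05 (limma), and 593 and 805 of these by at least 2-fold on the log2(RPKM + 1) scale, which understates the change of weakly expressed genes. With either knockout library left out the total of 3277 went to 1337 (without replicate 1) and 1284 (without replicate 2). The knockout libraries and DMSO replicate 2 were deposited on a longer transcript list than DMSO replicate 1. The list as a term compares the knockout with DMSO replicate 2, the same contrast as leaving out DMSO replicate 1. With the list term the balance turned, with 964 rises and 1440 falls. It turned too under median scaling (1842 and 1915), without DMSO replicate 1 (960 and 1441), without knockout replicates 1 (545 and 792) and 2 (568 and 716) and, barely, without MA4-022-2 (1364 and 1366). Without DMSO replicate 2 there were 1419 rises and 1042 falls.

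All 40 members of the G2/M and mitosis list fell in the knockout, among them UBE2C (-5.77), HMMR (-5.57) and PBK (-5.47). AURKB, the chromosomal passenger kinase, fell by 4.62 (SE 0.29, adjusted p = 1.41e-05, limma), from 30.7 RPKM in both DMSO libraries to 0.302 and 0.268, and MELK, a mitotic kinase, fell by 4.45 (SE 0.36, adjusted p = 4.79e-05, limma). Of 40 genes of DNA replication and G1/S, 39 fell (40 adjusted over the list alone), with CDC45 (-4.51), MCM10 (-4.08) and UHRF1 (-4.03) in front. Of 28 genes of nucleotide synthesis 16 fell (18 adjusted over the list alone), led by RRM2, the ribonucleotide reductase subunit, at -5.79 and TK1 at -4.12. Of 28 chromatin assembly genes 25 fell (26 adjusted over the list alone), including ASF1B (-4.82) and HJURP (-4.02). Of 22 p53 targets 19 rose and 0 fell (21 rose adjusted over the list alone), led by GDF15 and CDKN1A. All 5 lists passed the camera test at a preset inter-gene correlation of 0.01, with adjusted p of 1.22e-36, 1.54e-35, 3.31e-11, 3.61e-20 and 2.72e-14 in that order. With an estimated correlation none held on the deposited values (adjusted p = 0.209 for each of the 5), while under median scaling DNA replication and nucleotide synthesis did (adjusted p = 0.0327 each).

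In the BCL2 and IAP family 7 of 18 genes rose and 0 fell (the same count adjusted over the list alone; 4 without either knockout library), with the pro-apoptotic BBC3 (2.45), BMF (2.02) and BNIP3L (1.32); camera gave an adjusted p = 0.0123, and 0.533 with an estimated correlation. Of 29 androgen response genes 2 rose and 11 fell (3 and 13 adjusted over the list alone). The fallen included CENPN (-2.21), a centromere gene that belongs as much to the cell cycle. The count of falls went to 6 with the list term, 6 without DMSO replicate 1, 7 without DMSO replicate 2 and 6 without knockout replicate 2, and that of rises to 1 under median scaling, 0 without knockout replicate 1 and 7 without SG3-179. The camera call (adjusted p = 0.0286) was lost under median scaling (adjusted p = 0.0597) and with an estimated correlation (adjusted p = 0.552). KLK3, the gene of prostate-specific antigen, was at 2328 and 2188 RPKM in the knockout and 1049 and 1485 RPKM in DMSO. Among 18 luminal prostate genes 5 rose and 3 fell (the same adjusted over the list alone), with PSCA at 2.23 and KRT19 at -1.64; 3 rose with the list term or without DMSO replicate 1 or either knockout library, and 1 fell without DMSO replicate 2 or either knockout library.

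Of 30 MYC and nucleolar genes 1 rose and 9 fell in the knockout (12 fell adjusted over the list alone; 3 and 2 without knockout replicates 1 and 2), LYAR among them at -1.44, with a camera adjusted p = 0.000549, or 0.276 with an estimated correlation. MYC itself was at 101 and 78.3 RPKM against 94.9 and 83.0 RPKM in DMSO. Of the 14 histone and HEXIM1 genes that are known to rise under BET inhibition, 2 rose and 8 fell (the same adjusted over the list alone; camera adjusted p = 0.00101, or 0.240 with an estimated correlation); HIST1H2BJ fell by 5.71 and HIST1H2BG by 4.58. HEXIM1, the inhibitor of the elongation factor P-TEFb, rose by 1.06, a call lost without knockout replicate 1 (adjusted p = 0.0763). Interferon genes rose in 6 and fell in 2 of 18 (8 and 3 adjusted over the list alone). IFIT2 led them at 3.11 ± 0.45, although its 4.64 and 18.1 RPKM differed between the knockout libraries. Of 20 genes of the unfolded protein and ATF4 response 6 rose and 1 fell (the same adjusted over the list alone), with SESN2 at 2.52, and 2 rose with the list term and 2 or 3 when any 1 library of the pair of groups was left out. In the HOX clusters 1 of 12 rose and 3 fell (the same adjusted over the list alone), with HOXC13 at 1.28 and HOXA10 at -1.32, a call lost without knockout replicate 2 (adjusted p = 0.0513). The falls went to 0 without that library and to 5 without SG3-179.

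Sterol and fatty acid synthesis had 2 rises and 4 falls among 25 genes in the knockout (1, 0 and 0 falls without DMSO replicate 2 and knockout replicates 1 and 2; 0 rises with the list term or without DMSO replicate 1 or knockout replicate 1, and 4 without SG3-179). The BET, P-TEFb and kinase list had 2 rises among 13, CDK9 and HEXIM1, of which 1 was left with the list term or without DMSO replicate 1, knockout replicate 2 or MA4-022-2 and 0 without knockout replicate 1. Of 5 mesenchymal genes tested 0 passed; FN1 had the smallest p, at -1.23 ± 0.57 (adjusted p = 0.141, limma), and passed with the spread from 7 groups (adjusted p = 0.0367) and without SG3-179 (0.0251). In the neuroendocrine list 1 of 4 rose, TUBB3 at 1.26 (adjusted p = 0.0775 without knockout replicate 1 and 0.0546 without DMSO replicate 1, and lost with the list term). Of the lists for other cell types, the basal one had LAMB3 higher (1.42) and ITGA6 lower (-0.86, adjusted p = 0.225 without DMSO replicate 2 and lost too without either knockout library or MA4-022-2), and the stromal, blood and endothelial one had ACTA2 higher (2.10 ± 0.17), with 2 members tested in each.

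The 3 BET-kinase inhibitor libraries were compared with DMSO as a class. MYC fell, as did genes of ribosome biogenesis and DNA replication, while HEXIM1 and SERPINI1, known markers of BET inhibition, rose. The largest rises were SNORD118 (3.29 ± 0.51), ASNS, the asparagine synthetase (3.09 ± 0.85), SERPINI1 (2.94 ± 0.30), HEXIM1 (2.84 ± 0.20), the nuclear non-coding RNAs NEAT1 (2.80 ± 0.41) and MALAT1 (2.73 ± 0.36), KLHL24 (2.61 ± 0.29) and ADARB1 (2.58 ± 0.16). ASNS was at 72.1, 298 and 1073 RPKM in MA4-022-1, MA4-022-2 and SG3-179 against 31.2 and 34.3 in DMSO, and its call was lost without DMSO replicate 1 (adjusted p = 0.0953) or 2 (0.0997). The largest falls were 7 histone genes, from HIST1H1B (-4.56 ± 0.65) through HIST1H2AB, HIST1H2AL, HIST1H2AH, HIST1H4A and HIST1H3B to HIST1H2BM (-4.24 ± 0.24), and LINC00161 (-4.40 ± 0.21). Each gene named here was beyond both DMSO libraries in 3 of 3 inhibitor libraries, which the rule for naming them required.

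Of 12133 genes 1267 rose and 3814 fell under the BET-kinase inhibitors (adjusted p under 0.05, limma). The balance depended on the scaling. The median log2 fold change of all genes was -0.21, and with each library scaled to a common median 2552 rose and 2906 fell (46.8% rises against 24.9%); quantile normalization gave 2821 rises and 2633 falls. Among genes called both on the deposited values and under median scaling (4172), none changed direction. Genes called in only 1 of these fits were not checked for direction. All fold changes here are those of the deposited values, to be read against that median of -0.21. With the transcript list as a term, which compares these libraries with DMSO replicate 1 alone, 968 rose and 2506 fell.

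Of 30 MYC and nucleolar genes 27 fell and 0 rose under the BET-kinase inhibitors (29 fell adjusted over the list alone). MYC went from 94.9 and 83.0 RPKM in DMSO to 31.3, 25.7 and 16.0 (-1.87 ± 0.26, adjusted p = 0.000688, limma); NOP16 and DKC1, factors of ribosome maturation, fell by 2.59 and 1.94. All 40 DNA replication genes fell (also adjusted over the list alone), with UHRF1 at -3.87, MCM5 at -3.09 and MCM2 at -2.93. Of 28 nucleotide synthesis genes 25 fell (also adjusted over the list alone), led by RRM2 (-3.55). Of 28 chromatin assembly genes 24 fell (also adjusted over the list alone), and 17 with the list term. Of 40 G2/M genes 35 fell (37 adjusted over the list alone), with UBE2C at -2.54, AURKB at -2.42 ± 0.27 (adjusted p = 0.000234, limma) and MELK at -2.28 ± 0.33 (adjusted p = 0.000783, limma). That count went to 26 under median scaling, 18 with the list term, 23 without DMSO replicate 1 and 18 without DMSO replicate 2. Camera gave adjusted p of 1.72e-10, 8.19e-19, 8.57e-08, 3.90e-07 and 4.39e-07 for these 5 lists. With an estimated correlation no list held on the deposited values (adjusted p = 0.313, 0.313, 0.313, 0.550 and 0.733), while under median scaling the first 3 did (0.0428, 0.0440 and 0.0428).

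Androgen response genes rose in 2 and fell in 14 of 29 under the BET-kinase inhibitors (the same adjusted over the list alone; 1 rose with the list term; camera adjusted p = 0.0449, or 0.733 with an estimated correlation). The kallikreins KLK2 (-3.37 ± 0.42) and KLK3 (-2.77 ± 0.60) fell, KLK3 to 371, 249 and 65.0 RPKM, and so did ADAMTS1 (-3.19 ± 0.28). The call of KLK3 was lost without DMSO replicate 2 (adjusted p = 0.0642). Of 18 luminal genes 3 rose and 7 fell (4 and 8 adjusted over the list alone; 6 rose without SG3-179), including MSMB at -2.26 and KRT19 at -1.83. In the HOX clusters 9 of 12 fell and 0 rose (10 fell adjusted over the list alone; camera adjusted p = 0.00599, or 0.401 with an estimated correlation), HOXA10 by 2.96, HOXA11 by 1.66 and HOXB7 by 1.39, besides HOXB13.

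The histone and HEXIM1 list parted under the BET-kinase inhibitors, with 5 rises and 7 falls among 14 (the same adjusted over the list alone); its replication-dependent members HIST1H2BG and HIST1H2BJ fell by 3.29 and 3.17. Of the 13 BET, P-TEFb and kinase genes 3 rose, with BRD2 at 1.82 after HEXIM1, and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.0449, or 0.0538 under median scaling and 0.313 with an estimated correlation). The fallen gene, MEPCE at -0.53, was not called under median scaling (adjusted p = 0.145), nor without DMSO replicate 2, MA4-022-2 or either knockout library. Of 22 p53 targets 5 rose and 8 fell (7 and 6 under median scaling, 3 and 6 with the list term; 1 rose without DMSO replicate 1 and 3 without DMSO replicate 2 or either knockout library), TP53INP1 by 2.24 and AEN by -2.19, and CDKN1A was at 51.8, 64.3 and 60.4 RPKM against 45.6 and 51.6 in DMSO. In the BCL2 and IAP family 2 rose and 6 fell of 18 (4 rose under median scaling; 1 rose with the list term or without either DMSO library, either knockout library or MA4-022-2), BNIP3L at 1.40, BID at -1.44 and CFLAR, an inhibitor of caspase-8 activation, at -1.37. The interferon list had 2 rises and 5 falls of 18 (4 and 3 under median scaling, 2 and 3 with the list term; 1 rise without DMSO replicate 1 and 3 falls without DMSO replicate 2), OAS3 at -1.43 among them. The sterol list had 5 of each among 25 (9 rises and 4 falls under median scaling, 6 and 3 with the list term), with INSIG1 higher (1.63) and ELOVL6 lower (-1.23); 3 fell without DMSO replicate 2 or without MA4-022-2.

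Of 20 unfolded protein and ATF4 response genes 2 rose and 1 fell under the BET-kinase inhibitors, ASNS and VLDLR (1.05) against SDF2L1 (-1.65), with 1 rise with the list term or without either DMSO library, 10 rises without MA4-022-1 and 3 falls without SG3-179; camera gave an adjusted p = 0.0310, or 0.101 under median scaling and 0.762 with an estimated correlation. Of 5 mesenchymal genes 2 fell, THBS1 at -3.20 and SNAI2 at -1.12 (4 without SG3-179). In the neuroendocrine list TUBB3 and SYP rose (1.33 and 1.23) and DLL3 fell (-1.36). Neither list of other cell types had a called member. ITGA6 stood at 0.10 ± 0.25 and LYZ at -0.21 ± 0.15.

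**Figure D2:**
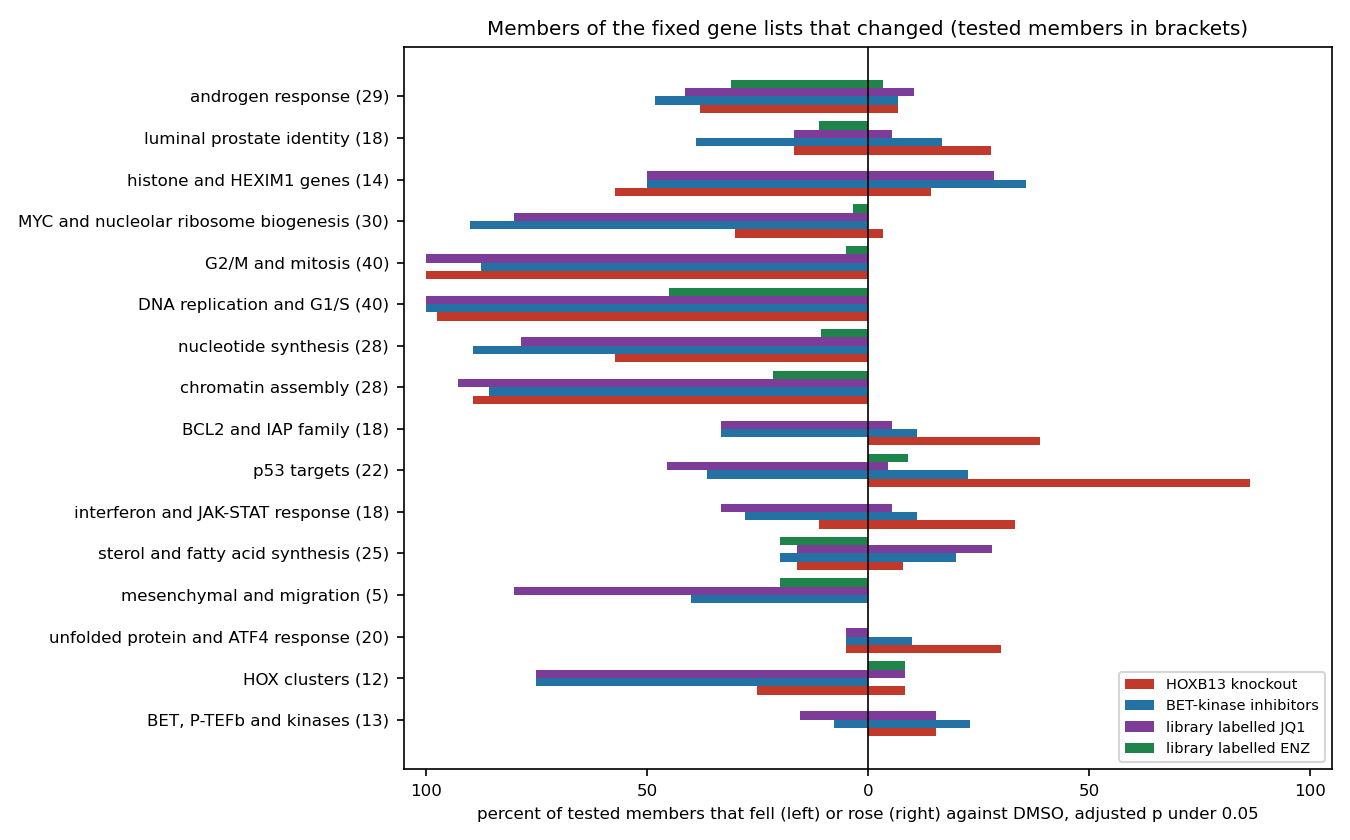
Percent of the tested members of 16 gene lists that rose (to the right of 0) or fell (to the left) against DMSO at an adjusted p under 0.05, with 1 bar per comparison and the number of tested members in brackets. In the p53 list 19 of 22 genes rose in the knockout and 5 under the BET-kinase inhibitors, while in the MYC and nucleolar list 9 and 27 of 30 fell.

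Genes changed in both comparisons are those the series asks for. Both rose 450 genes and both lowered 1153, against 177 and 496 for independent lists of these sizes, while 202 rose in the knockout and fell under the inhibitors (534 for independent lists) and 30 did the opposite (165). Thus 73.1% of the genes that fell in the knockout also fell under the BET-kinase inhibitors, and 26.5% of those that rose also rose. With median scaling 829 rose in both and 1196 fell in both (387 and 459 for independent lists), or 1196 of 1915 knockout falls (62.5%) and 829 of 1842 rises. The genes that fell most in both were the histone genes HIST1H1B, HIST1H2AB, HIST1H2AL (-6.01 and -4.33), HIST1H2AH, HIST1H4A (-5.91 and -4.27) and HIST1H3B. The 6 that rose most in both were SNORD118 (2.78 in the knockout and 3.29 under the inhibitors), MALAT1 (2.29 and 2.73), TP53INP1 (2.89 and 2.24), SAT1, the polyamine acetyltransferase (2.73 and 2.18), TXNIP, the thioredoxin inhibitor (2.42 and 2.14), and MAP1LC3B, an autophagy gene (2.14 and 2.38). SNORD118 was listed near 0 in both DMSO libraries.

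Both comparisons share the DMSO libraries, which alone raises their likeness. The correlation of fold changes over genes, which are not independent replicates, was 0.535, and simulated unchanged groups against the same controls gave 0.545. The covariance was 0.323 against a simulated 0.0344, a difference of 0.289. The simulations (50 draws) gave an overlap of 0 genes. They hold no changed gene, so few calls can arise in either comparison. That 0 therefore does not show what shared controls add where many genes change. With DMSO replicate 2 for the knockout and replicate 1 for the inhibitors the covariance was 0.304, and with the controls crossed 0.276. With no DMSO library in common, both values stayed near the difference of 0.289. This argues against chance values of the shared DMSO libraries as the source of the excess covariance. DMSO cannot be split with 2 libraries on each side, so each side rests on 1 DMSO library. Whatever both DMSO libraries have in common is still shared, and the count of shared genes was not examined in this way. The total of 1603 genes went to 1025 with the list term (192 rises and 833 falls, against 76.9 and 297 for independent lists), to 1023 without DMSO replicate 2, and to 771 and 704 without knockout replicates 1 and 2.

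**Figure D3:**
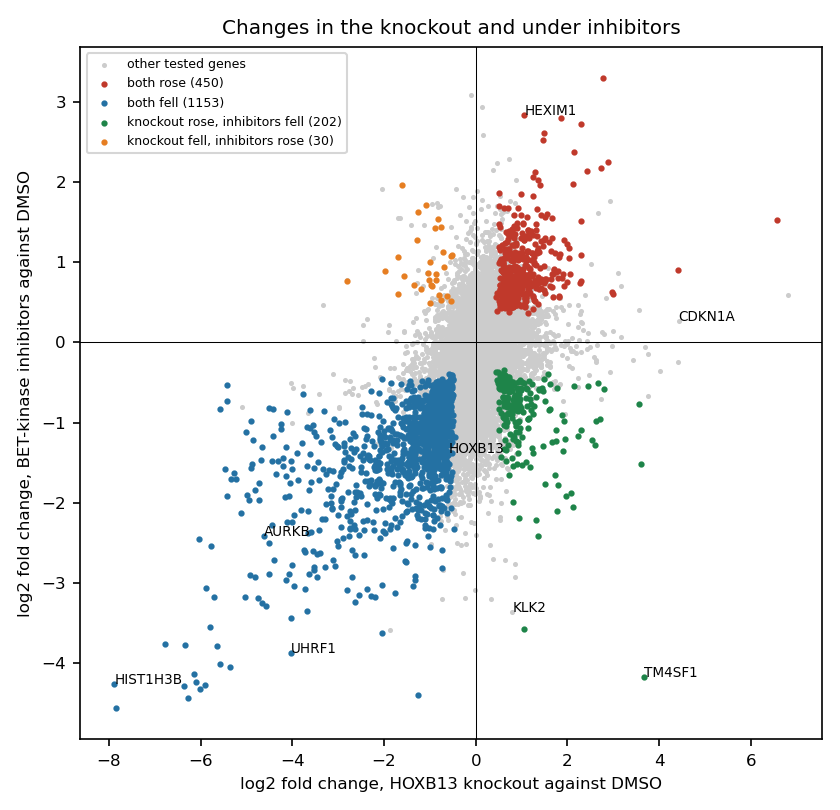
Log2 fold change against DMSO in the HOXB13 knockout (horizontal axis) and under the BET-kinase inhibitors (vertical axis) for each of 12133 genes, 1 point per gene. The 1153 genes that fell in both are in blue, the 450 that rose in both in red, and the 202 and 30 that went opposite ways in green and orange; other genes are grey.

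The library labelled JQ1 was compared with DMSO as a single library, which the test assumes to vary like the replicated groups. MYC was lower (-1.57 ± 0.35, adjusted p = 0.00929, limma), though not called under median scaling (adjusted p = 0.0727), and HEXIM1 rose (2.56 ± 0.26, adjusted p = 0.000275, limma). The largest rises were SNORD118 (3.81), NEAT1 (3.50), MALAT1 (3.27), TUBA1A (2.80) and TP53INP1 (2.74), and the largest falls UBE2C (-5.39), PBK (-5.27), HIST1H3B (-5.14), HIST1H1B (-5.14) and HIST1H2AB (-5.13). AURKB was at -3.87 and MELK at -3.80. SERPINI1 rose by 1.55, a call lost without DMSO replicate 1 (adjusted p = 0.0782), and KLK3 fell by 3.11, a call lost without DMSO replicate 2 (0.0921). FKBP5 (-1.15) and TMPRSS2 (-0.63) did not pass, TMPRSS2 doing so with 7 groups (adjusted p = 0.0336) and without SG3-179 (0.0302).

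In the library labelled JQ1 465 genes rose and 3549 fell (limma). The median log2 fold change was -0.37; median scaling gave 1429 rises and 2232 falls (39.0% rises against 11.6%) and quantile normalization 1817 and 1794. The total of 4014 went to 2650 without DMSO replicate 2, and the list term gave 358 rises and 2294 falls. All 40 G2/M and all 40 DNA replication genes fell, as did 24 of 30 MYC and nucleolar, 22 of 28 nucleotide synthesis and 26 of 28 chromatin assembly genes (40, 40, 27, 25 and 27 adjusted over the list alone). In the sterol list 7 of 25 rose and 4 fell (the same adjusted over the list alone; 4 rose without DMSO replicate 1 or either knockout library, 1 fell with the list term or without DMSO replicate 2, and 2 fell under median scaling and without either knockout library or MA4-022-2), with INSIG1 at 1.92. Camera called these 6 lists at a preset correlation, and none held with an estimated one (adjusted p from 0.305 to 0.312). Androgen response genes rose in 3 and fell in 12 of 29 (1 rose with the list term or without DMSO replicate 2), HOX genes in 1 and 9 of 12, and p53 targets in 1 and 10 of 22 (6 fell under median scaling, with the list term or without DMSO replicate 2).

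The library labelled JQ1 was set against the BET-kinase class to ask where the BET-kinase inhibitors differ from it. Mitotic genes were lower in the former. The 5 largest falls were HMMR (-3.91 ± 0.35), PBK (-3.68 ± 0.38), DLGAP5 (-3.60 ± 0.39), PLK1 (-3.41 ± 0.28) and PTTG1 (-3.36 ± 0.24). HMMR was at 1.60 RPKM in the library labelled JQ1 and at 27.7, 34.2 and 58.5 RPKM in MA4-022-1, MA4-022-2 and SG3-179. Of the 40 G2/M genes 24 were lower (39 adjusted over the list alone, 12 with the list term, 13 without either DMSO library, 15 without either knockout library; camera adjusted p = 3.90e-52, or 0.268 with an estimated correlation). TUBA1A (2.07), SNORD14D (2.03), SLC39A8 (1.55) and HADH (1.46) were higher. With no filter each of these lost its call, as did PBK and DLGAP5 among the falls. The median log2 difference of all genes was -0.16, and more genes were called higher under median scaling or quantile normalization than on the deposited values. TUBA1A was not called under median scaling (adjusted p = 0.0597), and SNORD14D and SLC39A8 were lost without MA4-022-2 (0.0757 and 0.0752). Without DMSO replicate 1 TUBA1A, SNORD14D and HADH lost their calls (0.0975, 0.0663 and 0.0866), and without knockout replicate 1 TUBA1A, SLC39A8 and HADH did (0.0781, 0.0651 and 0.0951); replicate 2 of either group gave the same losses. Only 6 genes were higher and 87 lower in all (limma), a total of 93 that went to 145, 54 and 192 without MA4-022-1, MA4-022-2 and SG3-179, to 53 without either DMSO library and to 45 without either knockout library. AURKB (-1.45, adjusted p = 0.121) passed without MA4-022-1 (0.0137) and without SG3-179 (0.0419), and MELK (-1.52, adjusted p = 0.211) without SG3-179 (0.0199). HEXIM1 (-0.28), MYC (0.30), KLK3 (-0.34), HOXB13 (-0.25) and SERPINI1 (-1.39) did not pass.

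In the library labelled ENZ, GDF15 (3.43), CD55, the complement decay factor (3.31), CTH (3.22), GTPBP2 (3.02) and BEST1 (2.99) rose most. Among the largest falls were NPPC (-3.27), KLK2 (-3.11), an androgen-induced gene, TM4SF1 (-2.90) and TRIB2 (-2.76). Of these 9 genes TM4SF1 alone kept its call without DMSO replicate 2, and KLK2 went from an adjusted p = 0.0273 to 0.116. TM4SF1 and BEST1 alone kept theirs without either knockout library, which enters here only through the spread. Without DMSO replicate 1, and also with no filter, GDF15, CD55, CTH, GTPBP2, NPPC, KLK2 and TRIB2 lost their calls as well. FKBP5 (-2.16, adjusted p = 0.0648), TMPRSS2 (-1.88, 0.125), KLK3 (-1.67, 0.252) and AURKB (-1.41, 0.0640) did not pass, and each passed with the spread from 7 groups (0.0266, 0.00323, 0.0176 and 0.00686, limma), as each did without SG3-179 (0.00264, 0.0145 and 0.00793 for the last 3). MYC (-0.12), HEXIM1 (-0.07), SERPINI1 (0.78) and MELK (-1.02) did not pass, MELK doing so with 7 groups (0.0211) and without SG3-179 (0.0105).

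Of the 29 androgen response genes 1 rose and 9 fell in the library labelled ENZ (1 and 16 adjusted over the list alone; 0 fell without DMSO replicate 2 and 17 without SG3-179). Of 40 DNA replication genes 18 fell (33 adjusted over the list alone; 2 without DMSO replicate 2, 4 without either knockout library, 9 without MA4-022-2 and 35 without SG3-179), and of 25 sterol genes 5 fell (14 adjusted over the list alone; 0 without DMSO replicate 2 or either knockout library, 2 without MA4-022-2 and 12 without SG3-179), with INSIG1 at -1.91. Of 28 chromatin assembly genes 6 fell (13 adjusted over the list alone; 3 and 0 without DMSO replicates 1 and 2, 1 without either knockout library or MA4-022-2, and 15 without SG3-179). None of the 20 ATF4 response genes passed among all genes, and 9 rose adjusted over the list alone (10 and 9 among all genes without MA4-022-1 and SG3-179); DDIT3 was at 208 RPKM against 10.9 and 13.4 RPKM in DMSO. Camera called each of these 5 lists at the preset correlation, and none held with an estimated one (adjusted p = 0.349, 0.349, 0.349, 0.450 and 0.450). In all, 154 genes rose and 278 fell (limma); median scaling gave 333 rises and 345 falls (49.1% rises against 35.6%). The total of 432 was 31 without DMSO replicate 2 and 29 with the list term, which left 0 androgen response, 1 DNA replication, 0 sterol and 0 chromatin assembly falls. Libraries outside this comparison moved it through the spread, to 59 and 58 without knockout replicates 1 and 2, 136 without MA4-022-2 and 1740 without SG3-179.

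The compounds of the BET-kinase class were compared with each other on 1 library each, with the spread taken from the DMSO and knockout pairs; whether MA4-022-1 and MA4-022-2 are different compounds or replicates of 1 is open, and doses and times are unknown. The 5 genes named next had the largest rises over MA4-022-1 in both of the others. SLC7A11, the cystine transporter, was at 0.627 RPKM in MA4-022-1, 37.7 RPKM in MA4-022-2 and 117 RPKM in SG3-179. It was higher in MA4-022-2 than in MA4-022-1 by 4.57 (95% interval 4.01 to 5.13) and in SG3-179 by 6.18 (5.62 to 6.74). CHAC1, NUPR1, DDIT3 and ATF4 were likewise higher in MA4-022-2 (3.78, 3.71, 3.65 and 3.08) and in SG3-179 (4.03, 4.62, 5.51 and 4.02) than in MA4-022-1. For MA4-022-2 the calls of all 5 genes were lost with no filter, and that of CHAC1 also with quantile normalization. For SG3-179 the call of CHAC1 was lost with no filter. In DMSO, DDIT3 was at 10.9 and 13.4 RPKM, above the 4.38 RPKM in MA4-022-1 and below the 66.6 and 244 RPKM in the other 2. Of 20 genes of this list 4 were higher in MA4-022-2 than in MA4-022-1 and 12 in SG3-179 (12 and 16 adjusted over the list alone; camera adjusted p = 4.07e-29 and 4.47e-17, or 0.391 and 0.341 with an estimated correlation).

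Of 29 androgen response genes 5 were lower in SG3-179 than in MA4-022-1 (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.13e-14, or 0.341 with an estimated correlation). KLK3 differed by -2.50 (95% interval -3.30 to -1.70), TMPRSS2 by -1.93 (-2.44 to -1.42), SPDEF by -2.51 and KLK4 by -2.21. The small nucleolar RNAs SNORA61 (-2.61) and SNORD14B (-2.60) were lower too. With no filter KLK3, TMPRSS2, SPDEF, KLK4, SNORA61 and SNORD14B all lost their calls. KLK4 and SNORD14B lost their calls under median scaling (adjusted p = 0.0612 and 0.0590). Of 40 G2/M genes 8 were higher in SG3-179 than in MA4-022-1 (33 adjusted over the list alone; camera adjusted p = 9.15e-18, or 0.341 with an estimated correlation). In all 130 genes were higher and 33 lower; the total of 163 was 4097 and 4091 without DMSO replicates 1 and 2, whose pair is then no longer part of the spread. Between SG3-179 and MA4-022-2 only HMOX1 (2.49) and LAMP3 (2.36) were higher and SNORA61 (-2.77) and SNORD50A (-2.38) lower (limma; 1776 genes at an unadjusted p under 0.05), and under median scaling 0 genes differed. Adjusted over the list alone, 28 G2/M and 9 ATF4 response genes were higher in SG3-179 than in MA4-022-2 (camera adjusted p = 5.84e-15 and 1.12e-08, or 0.566 for each with an estimated correlation). That total of 4 was 2845 and 2844 without DMSO replicates 1 and 2, and 118 without either knockout library. KLK3 (-1.92, 95% interval -2.72 to -1.12) did not pass in this pair, and did without either DMSO library (adjusted p = 0.00950 without replicate 1).

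Between MA4-022-2 and MA4-022-1 6 genes were higher and 0 lower (limma; 397 at an unadjusted p under 0.05), which became 43 without either DMSO library and 58 and 59 without knockout replicates 1 and 2. The log2 values of the 2 libraries correlated over genes at 0.988. HEXIM1 differed by -0.12 (95% interval -0.74 to 0.51), MYC by -0.27 (-0.89 to 0.35), HOXB13 by -0.40 (-0.97 to 0.18), KLK3 by -0.58 (-1.38 to 0.22) and AURKB by 0.49 (0.01 to 0.97), so differences of up to these bounds are not excluded. For SG3-179 against MA4-022-1 the differences were -0.45 (-1.07 to 0.18) for HEXIM1, -0.92 (-1.54 to -0.30) for MYC and 1.24 (0.71 to 1.76) for MELK, none of which passed the adjustment. MYC and MELK did without either DMSO library. MELK also passed with quantile normalization, at a mean of at least 5 RPKM and with pseudocounts of 0.1 and 0.5. HOXB13 differed by -0.82 in this pair, which did not pass in the main fit and did with quantile normalization.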

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

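The tests weighed here were all chosen after the result they bear on was seen. The test of the difference between knockout and BET-kinase inhibitors was part of finding the genes named here. With it, 202 genes rose in the knockout and fell under the inhibitors, and 30 fell and rose. The 4 with the widest difference of the first kind were TM4SF1, a tetraspanin-like surface protein (chromosome 3, 149369019 to 149377782; log2 difference 7.83 ± 0.19), ALDH3B2 (5.13 ± 0.22), SYT4 (4.63 ± 0.29) and RDH16 (4.33 ± 0.18). TM4SF1 was at 31.7 and 32.7 RPKM in DMSO, 404 and 434 RPKM in the knockout and 1.32, 0.670 and 0.609 RPKM in MA4-022-1, MA4-022-2 and SG3-179. It was also low in the library labelled ENZ (3.45 RPKM) and in that labelled JQ1 (0.449 RPKM). Of the second kind, PEG10 (-3.57 ± 0.27), an imprinted retrotransposon-derived gene, went from 11.1 and 9.04 RPKM in DMSO to 0.589 and 0.575 RPKM in the knockout and to 15.4, 13.3 and 27.2 RPKM under the inhibitors. DHRS2 (-3.57 ± 0.19) was at 0.295 and 0.348 RPKM in the knockout and at 15.9 and 16.6 RPKM under MA4-022-2 and SG3-179, and above both DMSO libraries in MA4-022-1 as well. In DMSO it was at 2.60 and 3.53 RPKM. It was above both in the library labelled ENZ (6.76 RPKM) but below both in that labelled JQ1 (0.904 RPKM).

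Genes present in 1 of the transcript lists alone were not tested. In the shorter list, LOC105374366 was at 37.1 RPKM or more in the BET-kinase libraries and 14.5 RPKM in DMSO replicate 1, LOC105374546 at 5.51 RPKM or more against 0.698 RPKM, and SNORA91 at 1.10 RPKM or more against 0.223 RPKM. In the longer list, ZNF812 was at 8.23 RPKM or more in the knockout and 2.36 RPKM in DMSO replicate 2. Each is compared with 1 control library, so that no spread of the control can be given.

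The histone genes fell together in 3 of the 4 comparisons with DMSO: of 47 tested genes of the replication-dependent clusters, 43 fell in the knockout (median -4.04), 43 fell and 2 rose under the BET-kinase inhibitors (median -2.90), 44 fell and 1 rose in the library labelled JQ1, and 0 changed in that labelled ENZ (median -0.34). Their messages carry no poly(A) tail, so a lower yield of such RNA could lower them in the preparation, but the lowest of 5 abundant structural RNAs without a tail (RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1) changed by -0.26 in the knockout and -0.45 under the inhibitors, and the median of 190 small nucleolar and Cajal body RNAs was 0.185 and 0.025, far above the fall of the histones. A lower share of cells in S phase, when these genes are transcribed, needs the DNA replication genes to fall as well, and 39 and 40 of 40 did. In the library labelled ENZ the median was -1.04 for the 40 replication genes and -0.34 for the histone genes, so the latter fell less there, on 1 library. Few changes of that size are called in a single library (23% of log2 changes of 1 in the simulated data). The lack of histone calls therefore does not decide whether the 2 sets are linked. A lower share in S phase may account for the fall in both, as a hypothesis; cell cycle phases were not measured, and a direct action of HOXB13 or BET proteins on the histone clusters was not tested.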

How the results depend on the processing

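The alternatives fixed beforehand and those added after seeing the data changed counts more than directions. Among the named genes no value that was called in the main fit or under the alternative changed direction. Values called in neither were not checked for direction. Of the values under alternatives, 1173 of 1235 kept their side of the threshold in HOXB13 knockout against DMSO and 1137 of 1170 in BET-kinase inhibitors against DMSO. The library labelled JQ1 kept 342 of 354 against DMSO and 286 of 317 against BET-kinase inhibitors, and the library labelled ENZ kept 263 of 336 against DMSO. The inhibitor pairs kept 184 of 191 in MA4-022-2 against MA4-022-1, 200 of 238 in SG3-179 against MA4-022-1 and 143 of 177 in SG3-179 against MA4-022-2. Count-based alternatives could not be run on RPKM. The cause of a change was not tested except where fewer genes or libraries entered.

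Fewer genes enter with a mean of at least 5 RPKM, which gave 1982 changed genes for HOXB13 knockout against DMSO (3277 before), 3324 for BET-kinase inhibitors against DMSO (5081), 236 for library labelled ENZ against DMSO (432) and 1038 for genes changed by both HOXB13 knockout and BET-kinase inhibitors (1603). A log2 fold change of at least 1 gave 1398, 1982, 2411 (library labelled JQ1 against DMSO, 4014 before) and 607 (both). The list term gave 2652 for the library labelled JQ1, 29 for that labelled ENZ, 1025 for both and 52 for library labelled JQ1 against BET-kinase inhibitors (93). For ENZ, 7 groups gave 1308 and median scaling 678. For JQ1 against the BET-kinase class, no filter gave 25 and a pseudocount of 0.1 gave 174.

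For differences among MA4-022-1, MA4-022-2 and SG3-179: MA4-022-2 against MA4-022-1 had 6 calls, and 0 with no filter, 10 at a mean of 5 RPKM and 16 at a pseudocount of 0.1. SG3-179 against MA4-022-1 had 163, and 370 with quantile normalization, 9 with no filter, 290 at a mean of 5 RPKM and 63 with the largest transcript. SG3-179 against MA4-022-2 had 4, and 0 with quantile normalization or median scaling, 1 with no filter, 33 at a mean of 5 RPKM, 8 at a pseudocount of 0.1 and 2 with the largest transcript.

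Leaving out 1 DMSO, knockout or BET-kinase library at a time, also where it enters only through the shared spread, gave 1284 to 4647 changed genes for the knockout, 3478 to 6021 for the BET-kinase inhibitors, 704 to 2330 for both and 2650 to 5358 for JQ1. It gave 31 to 1740 for ENZ (59 and 58 without the knockout libraries, 136 without MA4-022-2) and 45 to 192 for JQ1 against the BET-kinase class (53 without either DMSO library). The highest of each of these was without SG3-179. For the inhibitor pairs it gave 43 to 59, 242 to 4097 and 118 to 2845, in the order above. A group left with 1 library is assumed to vary like the others.

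Camera called 9, 9, 8, 8 and 8 lists in the 5 comparisons, and 0 in each with an estimated correlation (with median scaling as well, 2 for the knockout, 3 for the BET-kinase inhibitors and 0 in the others); leaving out a library gave 9 to 12, 7 to 9, 6 to 8, 8 to 9 and 6 to 10. The replicate number as a block gave 4652 changed genes for the knockout, 6255 for the BET-kinase inhibitors and 2290 for both, and 10 and 9 lists. DMSO has 2 libraries and the BET-kinase class 3, and SG3-179, numbered 3, has no DMSO library of its number. The block therefore pairs only the other 2 of that class, and 6255 and 2290 do not describe SG3-179. With no block, only the groups compared gave 4144 for the knockout and 4153 for the BET-kinase inhibitors. Leaving out SG3-179 alone, also with no block, gave 6021 for the latter and 2330 for both. How much of the higher counts comes from the block itself was not tested. Deviations of same-numbered libraries correlated at 0.274 and 0.18 in 2 pairs of groups, too few to say that the numbers pair the samples. At 14.5 to 20.4 M reads, the JQ1 and BET-kinase libraries limit what can be called among weakly expressed genes.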

Other observations

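The tests weighed in this part were all chosen after the results were seen. The genes lowered by both the knockout and the BET-kinase inhibitors were followed in the other libraries. Of 1153, 1082 fell in the library labelled JQ1 (median -1.54) and 185 fell and 4 rose in that labelled ENZ (median -0.59, against -0.01 for all genes). Of the 450 raised by both, 192 rose in the library labelled JQ1 and 42 in that labelled ENZ. These comparisons use the same DMSO libraries as those that picked the genes.

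Why so many genes fell in both is open. Chance values of the shared DMSO libraries would need the covariance of fold changes to vanish with separate controls, and the lower of its values was 0.276 against a simulated 0.0344. A p53 response common to both would need p53 targets to rise under the BET-kinase inhibitors, where 5 of 22 rose and 8 fell, but 7 rose and 6 fell under median scaling, so it stays open. A fall shared with slowed growth under another drug remains possible: among genes picked with 1 DMSO library and examined against the other, 82.4% were lower in the library labelled ENZ (43.4% of all genes) and, the other way round, 90.3% (57.6% of all genes), so part of the overlap may not be special to HOXB13 loss and BET inhibition. A shared HOXB13 and BET programme also stays open, untested here, with HOXB13 lower under the BET-kinase inhibitors than in the knockout (log2 difference 0.79, adjusted p = 0.0238, limma).

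The titles and treatment entries of the libraries titled JQ1 and ENZ contradict each other. HEXIM1, which BET inhibitors raise, was higher by 2.63 on the log2 scale in the library titled JQ1 than in that titled ENZ, against an exchange of the titles. The log2 difference of the library titled JQ1 from that titled ENZ correlated over genes with that of the BET-kinase inhibitors from DMSO at 0.564 (0.317 to 0.652 for single inhibitor and DMSO libraries), with no library in both differences. An exchange of the treatment entries is therefore the likely reading, as a hypothesis, since only expression was used to weigh it.

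Transcripts of fibroblasts and matrix, looked up after some had been seen, were highest in DMSO replicate 2 for 7 of 7 genes. POSTN was at 1.93 RPKM there and at 0 in DMSO replicate 1, COL3A1 at 1.08 and 0.00723 RPKM, TIMP1 at 1.03 and 0.0433 RPKM, and COL1A1 at 0.910 and 0.161 RPKM; SPARC, DCN and LUM reached 0.829, 0.198 and 0.158 RPKM in that library.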
